A study of Danio rerio with 9 samples.

How the data were processed

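Gene expression was measured by bulk RNA-seq in 9 libraries of sorted zebrafish embryo cells, 3 libraries in each of 3 groups. The groups were mCherry-positive cardiac neural crest and mCherry-negative non-crest cells, both at 17 h post-fertilisation, and GFP-positive trunk neural crest at 24 h. Groups and replicate numbers were taken from the sample labels. The labels' protocols name a SMART-Seq v4 full-length cDNA kit, whose amplification leaves no molecular identifiers, and single-end sequencing. Reads are therefore not independent molecules, and every counting interval or floor printed here covers counting error only. Nothing in the labels says that replicates came from separate pools of embryos, so p-values measure the spread between these libraries, which may be technical.

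The authors aligned reads with Bowtie2 to GRCz10 and counted them with featureCounts from Subread, per the submitters' processing notes. The count table for cardiac crest and non-crest held raw read counts per gene, made with featureCounts version 1.5.1 on Ensembl release 80 gene models, per the file headers. Counting ran over whole gene bodies, introns included, with no strand option, per the file headers. All 4819 genes that lie wholly inside another gene held 0 reads in the 6 libraries, as did 7.34% of the genes that share no base with another. Overlapping and antisense genes are therefore uncertain, and the overlapped share is given where a named gene has a marked one.

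The second deposited table held 20847 genes for cardiac crest and trunk crest as a normalised signal, each gene's read count divided by a size factor of its library. The processing notes name DESeq without a version. Dividing each library's values by its smallest non-zero value gave whole numbers for 100% of the values in all 6 libraries (tolerance 0.02). For the 3 cardiac crest libraries these equalled the raw counts for all 20847 genes. The same table carried the authors' log2 fold changes with standard errors and their p-values, which are quoted only as the authors' deposited table. It omits 11106 genes of the count table. Of the 125 omitted genes with at least 100 reads over the cardiac crest libraries, 102 had over 75% of their depth-scaled reads in 1 library, in 86 cases cardiac crest replicate 3, against 454 of 16176 listed genes. Values were compared only within a table.

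The count table held 44672047, 34062539 and 40345294 reads for cardiac crest replicates 1, 2 and 3, and 35701534, 36371620 and 45172404 for non-crest. Reads recovered for trunk crest came to 29842884, 27664247 and 25128422 over the listed genes. The 10 most abundant genes took between 9.4% and 15.6% of a library in the count table, and between 9.4% and 12.5% in the second. Symbols came from the deposited table for 17643 of 31953 gene identifiers and from a reference table for 8806, while 5504 stayed unnamed. The deposited table held 15 symbols turned into dates, which were ignored. Coordinates are those of the count table on GRCz10. No genome sequence was used here.

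Cardiac crest was compared with non-crest by edgeR's quasi-likelihood test with robust estimation, on TMM-normalised counts of the 6 libraries, after edgeR's default expression filter. Cardiac crest was compared with trunk crest by limma on log2(value + 1) of the deposited values, with a variance trend and robust prior and no filter. The design fixed beforehand had assumed counts for this table, and limma on the log scale was its stated fallback for other units. Fold changes of low genes are understated on that scale. Benjamini-Hochberg adjusted p-values below 0.05 counted as calls. Standard errors against trunk crest are limma's, for the log2 fold change. Against non-crest, the value given as SE is the size of the log2 fold change divided by the square root of edgeR's quasi-likelihood F. It is derived from the test and is not the same quantity as limma's. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 24 lists with at least 3 tested members, and again with the correlation estimated per list. The ribosomal protein list took in 11 S6 kinase genes by name. Of the 25 lists, the mitochondrial genome list matched 0 genes and was not tested. Levels against non-crest are in CPM, reads scaled to the library total, and levels against trunk crest in size-factor-scaled reads. A fold against a group with 0 reads was computed against a floor of 3 reads over the group, and a ratio to a group with 1 to 3 reads has a 95% counting interval.

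Groups, lists, tests, alternatives and the rule for naming genes were chosen before the data were examined. The rule took 5 check genes (sox10, foxd3, crestin, tfap2a and ets1). Per comparison, it took the 10 higher and 10 lower genes with the largest log2 fold change among those past the test, at 10 CPM or more in the higher group, with non-overlapping libraries and a gene symbol that is not provisional. It also took up to 4 members of each list with the smallest adjusted p, and the 10 leading genes higher in both comparisons. Only part of these are named. Genes named outside the rule are said to have been chosen after their values were seen. Of the check genes, foxd3 could not be measured, since 98% of its bases lie inside another gene and 1 read was counted, and crestin matched no gene.

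Both tests were run on simulated counts drawn from the real means and library sizes, with 200 genes changed by a known fold. Against non-crest, 19683 genes entered the step, and 0%, 14.6%, 36.7% and 48% of the genes changed 2-, 4-, 8- and 16-fold were called, with 6 calls among 19468 unchanged genes. Against trunk crest, with 20847 genes, the shares were 0%, 30%, 48% and 80%, with 8 calls among 20627. Far more genes, 4829, passed in the real trunk comparison, where the adjusted threshold is less strict, so these shares do not describe it. A simulated list of 20 genes shifted 4-fold was called in both comparisons, and 0 of the 23 unchanged lists were. Simulated genes were drawn independently of each other, so this could not show false list calls that arise from correlated genes.

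Alternatives covered RLE and upper-quartile scaling, DESeq2, limma-voom, other expression filters, a stricter threshold of 0.01, a test against a log2 fold change of 1, the replicate number as a block, the estimated correlation and leaving out each library in turn. Those added after seeing the data were edgeR on the recovered reads, limma without the trend and robust prior, a pseudocount of 10, TMM factors for the trunk table, upper-quartile scaling in the list tests, leaving out replicate 3 of both groups, and leaving out genes that share bases with another. Cardiac crest libraries served both comparisons, so 20 sets of unchanged libraries were simulated for all 3 groups around a single mean per gene, and both tests were run on each set. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.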

Results

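The 9 libraries compared neural crest of 2 axial levels with each other and with neighbouring tissue. Neural crest is the migratory embryonic population that gives rise to pigment cells, peripheral neurons and glia and much of the head skeleton, and its cardiac part contributes to the heart. Cardiac crest cells (n = 3 libraries) were sorted for mCherry at 17 h post-fertilisation from tissue between the midbrain-hindbrain boundary and somite 6. The cells came from a fish line in which sox10 regulatory sequence drives the reporter. The labels give the 16-somite stage, while the deposited count table is named for 20 somites, and the labels were followed. Non-crest cells (n = 3) were the mCherry-negative cells of that tissue. Trunk crest cells (n = 3) were sorted at 24 h for GFP under a sox10 promoter in another line, from somites 7 to 16. Libraries of the count table held between 34062539 and 45172404 reads in genes, and the trunk crest libraries between 25128422 and 29842884 in the genes listed for them.

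Against non-crest cells of the same tissue, cardiac crest cells held more transcripts of the crest regulators sox10 and ets1 and far fewer of the skin gene krt5 and the vessel gene cdh5. Transcripts of sox10, the gene whose regulatory sequence drives the sorted reporter, stood at 350.8 ± 100.9 CPM (SD, n = 3) in cardiac crest. In non-crest they stood at 21.1 ± 10.6 CPM, a log2 fold change of 4.12 ± 0.47 (SE). The sort selected for sox10 reporter signal, so this rise checks the sort and is not an independent finding. For ets1, a transcription factor of cranial and cardiac crest, the levels were 186 ± 68.4 and 20.2 ± 10.2 CPM (3.29 ± 0.49). The epidermal keratin gene krt5 lay at 4.60 ± 0.685 CPM in cardiac crest and 939 ± 209 CPM in non-crest (-7.68 ± 0.41). For cdh5, encoding the adherens junction cadherin of endothelium, levels were 0.371 ± 0.236 and 41.1 ± 7.64 CPM (-6.75 ± 0.69), with 47.24% of its bases inside another gene.

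Of 19648 genes tested, 294 differed by edgeR's quasi-likelihood test, 57 higher and 237 lower in cardiac crest, and 54 of the 294 share bases with another gene. In 3343 genes (17.01%) all libraries of one group lay above all of the other, where chance gives 10%. The edgeR adjusted p was 0.00555 for sox10 (chromosome 3, 2013057 to 2022138, GRCz10), 0.0179 for ets1 and 0.000528 for krt5. Non-crest replicate 3 stood apart, with a Pearson correlation of 0.842 and 0.841 to the other non-crest libraries on the log scale, across genes, against 0.8995 between those, and 8.92 CPM of sox10 where they had 27.6 and 26.8. Without it and cardiac crest replicate 3, an alternative added after seeing the data, 752 genes differed, 264 of them among the 294. Leaving out cardiac crest replicate 1 or 2 gave 102 or 93 genes, and leaving out non-crest replicate 1 or 2 gave 171 or 163, while DESeq2 called 1050. With the replicate number as a block 284 genes differed, 221 of them among the 294. Of the 31 named genes past the test here, 11 passed without any 1 of the libraries, and 20 were lost in at least 1 such fit, the highest adjusted p being 0.233 for kctd15a without cardiac crest replicate 1. The 11 were gh1, sox10, olfcg1, vps13d, krt5, krt4, agr1, icn, mia, clec14a and cdh5.

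The steepest rise among named genes was in gh1, the growth hormone gene (ENSDARG00000038185, chromosome 3, 22197190 to 22202365), at 2074 ± 964 CPM in cardiac crest and 0.177 ± 0.0324 CPM in non-crest. Its 244774 reads in cardiac crest faced 21 in non-crest (log2 fold change 13.48 ± 0.72, edgeR adjusted p = 0.000528). Whether these reads came from the gene or from a transgene of the mCherry line could not be told. Next came ttpa, the tocopherol transfer protein gene (7.20 ± 1.14), mocos, encoding a molybdenum cofactor sulfurase (6.68 ± 1.09), the leukotriene receptor gene cysltr1 (5.91 ± 0.83) and cdh19, a cadherin gene of crest derivatives (5.20 ± 0.65). The edgeR adjusted p of these 4 ran from 0.00797 for cdh19 to 0.0258 for mocos, and each of the 4 passed 0.05 in the full set but not without cardiac crest replicate 1, where they stood between 0.0522 and 0.117. Also higher were inka1a (4.08 ± 0.58) and olfcg1 (304 ± 47.3 and 16.2 ± 8.54 CPM), an olfactory receptor gene of which 15.35% overlaps another gene. Reads in introns count toward a gene here, so transcripts of repeats inside olfcg1 or vps13d would count as theirs, which was not examined. Among the lowest, clec14a, an endothelial lectin gene, had 0 reads in cardiac crest and 7254 in non-crest, at least 2483-fold lower. With 0 reads against 1845, fut9d was at least 588-fold lower, and mia, with 1 read against 4479, was 4243-fold lower (95% counting interval 762 to 167597). Levels of agr1, a gene of the epidermis list, were 0.813 ± 0.658 CPM in cardiac crest and 880 ± 227 CPM in non-crest.

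**Figure D1:**
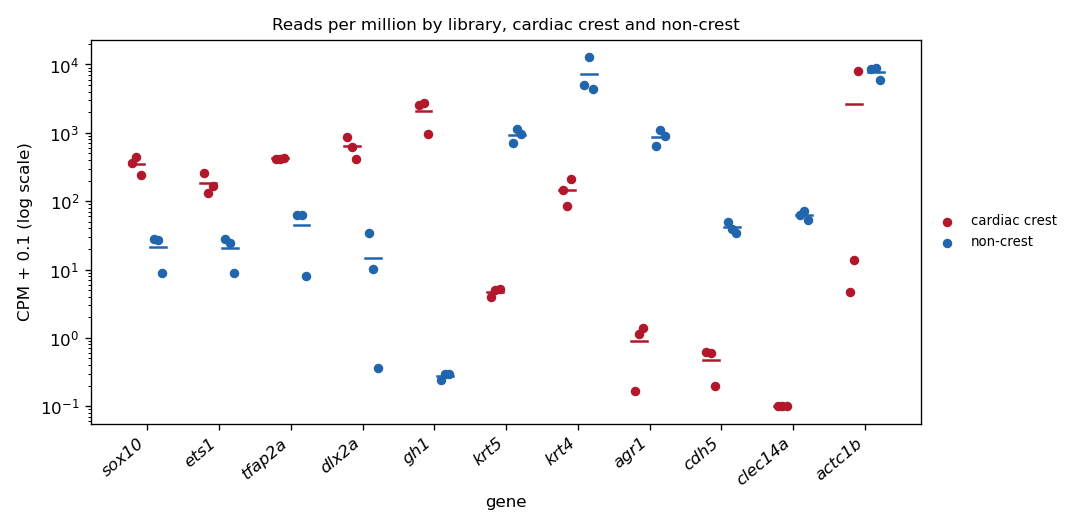
CPM plus 0.1 on a log axis for 11 genes, 1 point per library and a bar at each group mean, cardiac crest in red and non-crest in blue. For sox10 all cardiac crest libraries lie above all non-crest libraries, and for krt5, cdh5 and clec14a they lie below. The actc1b points, chosen after their values were seen, show cardiac crest replicate 3 among the non-crest libraries.

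At the preset correlation 4 crest lists were higher in cardiac crest, mostly through members short of the single-gene test. In the core crest list 2 of 18 tested members rose (sox10, on whose reporter the cells were sorted, and ets1). Of the others 0 fell and 16 did not pass, and 9 members rose when adjusted over the list alone. Its median log2 fold change was 1.26 (camera adjusted p = 6.31e-05; adjusted p = 0.143 with an estimated correlation). The edgeR call of ets1 was lost without cardiac crest replicate 1 (0.0744) or 2 (0.0513) or non-crest replicate 1 (0.0571) or 2 (0.0649). Transcripts of tfap2a, an early crest regulator, were at 424 ± 9.16 and 44.3 ± 31.4 CPM (3.35 ± 0.65, edgeR adjusted p = 0.0510, and 0.00376 without non-crest replicate 3). For twist1a the log2 fold change was 2.08 ± 0.52 (edgeR adjusted p = 0.136). Of 22 pigment genes 0 passed, 5 rose when adjusted over the list alone, and the median was 0.91 (camera adjusted p = 0.000567; adjusted p = 0.342 with an estimated correlation), the melanosomal receptor gene gpr143 standing at 3.24 ± 0.65. Of 24 genes of ectomesenchyme and pharyngeal arches 0 passed, 6 rose when adjusted over the list alone, and the median was 0.57 (camera adjusted p = 0.0128; adjusted p = 0.193 with an estimated correlation). Its member dlx2a had 632 ± 227 and 14.8 ± 17.5 CPM (5.54 ± 1.33, edgeR adjusted p = 0.117, and 0.0189 without non-crest replicate 3). In the list of cardiac crest candidates 1 of 14 rose (ets1) and 4 did when adjusted over the list alone, with a median of 0.67 (camera adjusted p = 0.0164; adjusted p = 0.193 with an estimated correlation). Several of its members were marked by the authors on these samples, so its direction is not independent evidence. The candidate list lost its call without cardiac crest replicate 2 (0.0560), non-crest replicate 1 (0.0597) or 3 (0.0657). It was also lost without replicate 3 of both groups (0.0756), an alternative added after seeing the data. The arch list was lost without cardiac crest replicate 2 (0.0614) or non-crest replicate 1 (0.0597).

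Most lists of other tissues were lower at the preset correlation, placode and notochord lists aside. Among 22 endothelial and blood genes 11 fell, 0 rose and 11 did not pass, 15 fell when adjusted over the list alone, and the median was -3.57 (camera adjusted p = 1.23e-19; adjusted p = 0.0586 with an estimated correlation). They included fli1b, an ETS factor gene of endothelium (-5.07 ± 0.65), and the vascular growth factor receptor gene kdrl (-2.77 ± 0.40). In the epidermis list 7 of 18 fell and 0 rose, 12 fell when adjusted over the list alone, and the median was -3.54 (camera adjusted p = 7.45e-15; adjusted p = 0.143 with an estimated correlation). Keratin gene krt4 had 147 ± 62.1 and 7336 ± 4630.1 CPM, and icn 2.19 ± 1.38 and 127 ± 74.0 CPM. In the cardiac mesoderm list 1 of 19 fell, tnnt2a, the cardiac troponin T gene (-4.27 ± 0.77), 2 fell when adjusted over the list alone, and the median was -1.91 (camera adjusted p = 0.00903; adjusted p = 0.509 with an estimated correlation; 0.109 without non-crest replicate 1). In the somite and muscle list 0 of 23 passed, 0 when adjusted over the list alone, with a median of -2.02 (camera adjusted p = 2.96e-08; adjusted p = 0.259 with an estimated correlation). Cardiac crest replicate 3 stood apart here: actc1b, a striated muscle actin gene chosen after its values were seen, was at 4.54, 13.8 and 7953 CPM in cardiac crest and at 8552, 8979 and 5838 CPM in non-crest. For desma, the desmin gene, the log2 fold change was -2.77 ± 1.04 (edgeR adjusted p = 0.363, and 0.0119 without that library).

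Neural tube genes had a median of -1.10, with 0 of 23 past the test and 1 lower when adjusted over the list alone (camera adjusted p = 0.00402; adjusted p = 0.632 with an estimated correlation). That call was lost without cardiac crest replicate 2 (0.0562) or non-crest replicate 2 (0.0569). The Delta ligand gene dld stood at -1.71 ± 0.35 (edgeR adjusted p = 0.0643). Of 10 endoderm genes 0 passed, 3 fell when adjusted over the list alone, and the median was -1.17 (camera adjusted p = 0.00622; adjusted p = 0.193 with an estimated correlation), hhex standing at -6.22 ± 1.64. In the retinoic acid list 1 of 26 rose, the retinoid receptor gene rxraa (2.11 ± 0.36), while the list as a whole was lower, with a median of -0.73 (camera adjusted p = 0.00928; adjusted p = 0.193 with an estimated correlation). Adjusted over the list alone, 1 rose and 3 fell, and the call was lost without non-crest replicate 3 (0.1004). The retinoic acid binding gene crabp1a was at 0.821 ± 0.395 and 7.73 ± 1.90 CPM (edgeR adjusted p = 0.0517).

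The other 13 lists did not pass camera. In the placode and ear list 1 of 16 rose (sox10, on whose reporter the cells were sorted), 1 when adjusted over the list alone (median 0.68, camera adjusted p = 0.104). In the migration and matrix list 2 of 41 rose, the semaphorin receptor gene nrp2a (2.29 ± 0.32) and the cadherin gene cdh6 (2.06 ± 0.30), and 4 when adjusted over the list alone. Its median of -0.18 and mean of -0.03 were negative where the test pointed up (adjusted p = 0.590). In the BMP and TGF-beta list 1 of 27 rose, id2a (780 ± 281 and 163 ± 55.7 CPM), and 3 when adjusted over the list alone, with a median of -0.08 against a mean of 0.07 and a test pointing up (adjusted p = 0.461). FGF targets, with 0 of 20 past the test on either adjustment, had a median of -0.11 against a mean of 0.29 and a test pointing up (adjusted p = 0.659). No member passed in the 9 remaining lists. Adjusted over the list alone, 2 of 24 Notch genes fell (median -0.40, adjusted p = 0.211) and 2 of 17 Wnt targets rose (0.03, adjusted p = 0.461), while the remaining 7 lists again had 0. These were neural and glial derivatives (25 genes, median -0.28, adjusted p = 0.461), early-response and stress genes (30, 0.35, adjusted p = 0.126), cell cycle (31, 0.01, adjusted p = 0.941) and notochord and floor plate (11, -0.04, adjusted p = 0.813). The last 3 were anterior Hox (4, -0.21, adjusted p = 0.721), posterior Hox (9, -1.08, adjusted p = 0.277) and the ribosomal protein list (91, -0.11, adjusted p = 0.625), whose 97 members matched by name include 11 S6 kinase genes. Leaving out cardiac crest replicate 3 brought early-response (0.00207), posterior Hox (0.00954) and neural and glial genes (0.0442) past 0.05 by camera, and leaving out non-crest replicate 3 brought Notch genes (0.00348) past it. The placode list passed without cardiac crest replicate 1 (0.04003) or non-crest replicate 2 (0.0135), and early-response genes without the latter (0.0227). The ribosomal protein list passed as lower without cardiac crest replicate 1 (0.0402) or non-crest replicate 2 (0.0135) and as higher without non-crest replicate 3 (0.0358). With an estimated correlation 0 of the 24 lists passed, and 5 had an unadjusted camera p below 0.05.

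**Figure D2:**
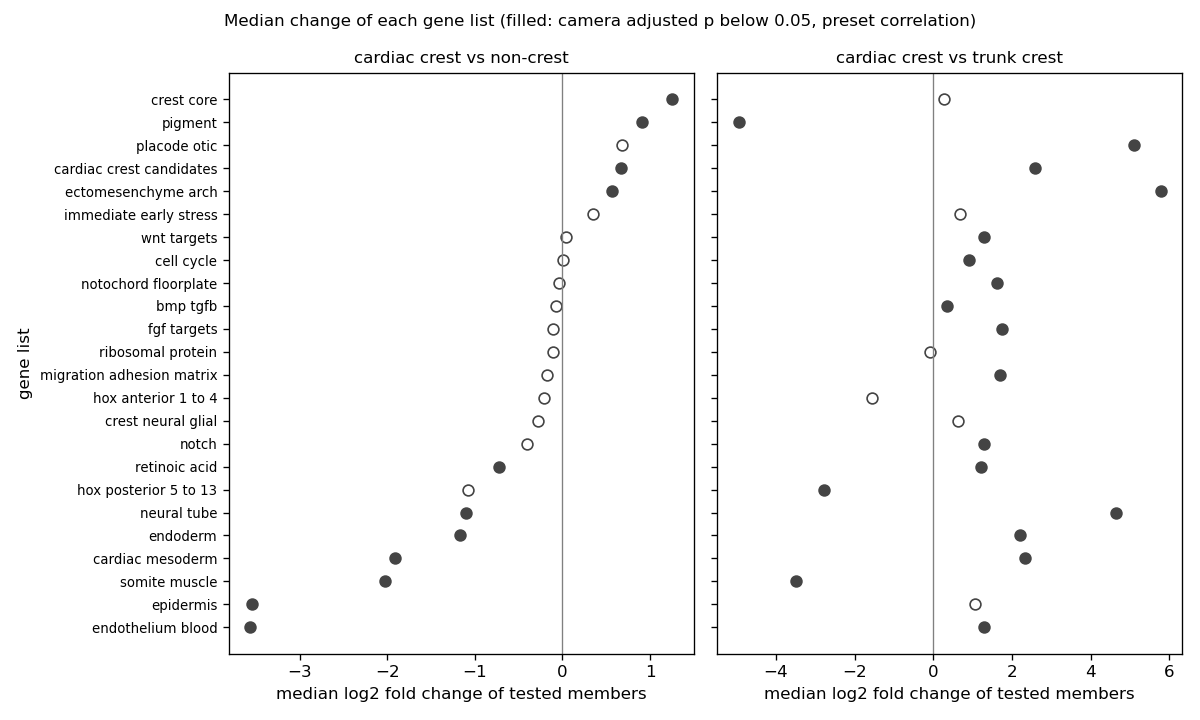
Median log2 fold change of the tested members of each of 24 gene lists (x axis), cardiac crest against non-crest on the left and against trunk crest on the right. Filled points passed camera at the preset correlation, 11 lists on the left and 18 on the right, and the pigment list lies at 0.91 on the left and -4.95 on the right.

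Against trunk crest, cardiac crest cells held more transcripts of the mesenchyme and arch genes pdgfra and dlx2a and fewer of the pigment gene dct and the posterior Hox gene hoxb9a. Transcripts of pdgfra, a growth factor receptor gene of mesenchyme, were at 5344 ± 998 scaled reads (SD, n = 3) in cardiac crest and 23.5 ± 13.4 in trunk crest, a log2 fold change of 7.95 ± 0.50 (SE). For dlx2a, a homeobox gene of the pharyngeal arches, levels were 18407 ± 7745 and 97.9 ± 77.9 (7.83 ± 0.61). The melanin synthesis gene dct was at 6.15 ± 2.97 in cardiac crest and 37498 ± 8231 in trunk crest (-12.44 ± 0.40). Posterior hoxb9a was at 1716 ± 363 and 12822 ± 1282 (-2.92 ± 0.22). The groups also differ in age, fish line, reporter and library series, which cannot be told apart from axial level, and each library series holds samples of 1 crest level only.

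Of 20847 genes tested with limma, 4829 differed, 2233 higher and 2596 lower in cardiac crest, and 940 of them share bases with another gene. Upper-quartile factors turned that balance round, with 2669 higher and 2307 lower. All libraries of one group lay above the other in 9180 genes (44.04%, where chance gives 10%). Limma adjusted p was 2.92e-05 for pdgfra (chromosome 20, 22535507 to 22576582, GRCz10), 7.96e-05 for dlx2a, 2.62e-06 for dct (chromosome 9, 53788137 to 53813085) and 6.24e-05 for hoxb9a. The higher count was 1333 without cardiac crest replicate 1 and 1344 without replicate 2, and the total was 3205 without replicate 2. The authors' deposited table lists 2894 genes higher in cardiac crest and 3099 higher in trunk crest at an adjusted p below 0.05.

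Genes near absent from trunk crest led the higher side. The gh1 gene had 244774 reads in cardiac crest and 2 in trunk crest, 68140-fold higher after scaling (95% counting interval 18863 to 562656). Trunk crest cells came from another fish line, so a transgene source of the gh1 reads stays open here too. With 0 reads in trunk crest, the neural progenitor gene sox19a was at least 3891-fold higher, and the Iroquois genes irx1b and irx7 at least 962-fold and 649-fold. Crest cells were not told apart here from other cells that the cardiac crest sort may have held. The proneural gene neurod1, with 2 reads in trunk crest, was 2121-fold higher (587 to 17514), and the apelin receptor gene aplnra, with 1, was 2530-fold higher (454 to 99913). For mafba, a hindbrain and crest transcription factor gene, levels were 5077 ± 991 and 10.1 ± 12.2 (log2 fold change 9.77 ± 0.98, limma adjusted p = 0.000282). Against non-crest cells of the same tissue mafba was not called (log2 fold change 1.09, edgeR adjusted p = 0.244). At the other end lay pigment genes: tyrp1b (-13.09 ± 1.56), the iridophore purine gene pnp4a (-10.74 ± 0.64), and gch2, a pteridine synthesis gene at 674 ± 520 and 1569730 ± 69680 scaled reads (-11.45 ± 0.43). Gap junction gene cx30.3 (-12.46 ± 1.02), transporter gene slc22a7a (-11.62 ± 0.40) and fast muscle troponin gene tnni2a.4 (-11.25 ± 0.64) were also among the 10 lowest. Muscle transcripts were high in every trunk crest library, as given below, and were not traced to crest cells.

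**Figure D3:**
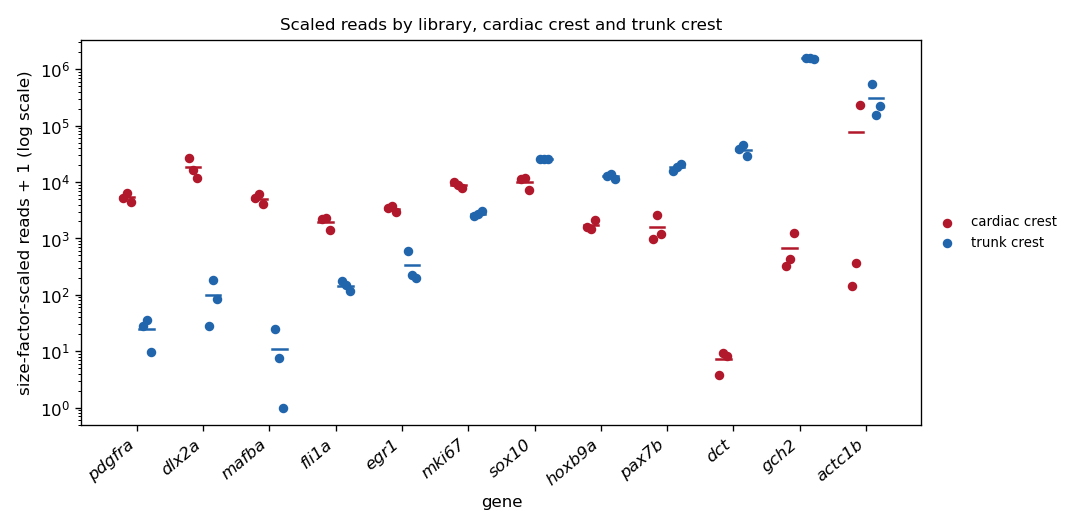
Size-factor-scaled reads plus 1 on a log axis for 12 genes, 1 point per library and a bar at each group mean, cardiac crest in red and trunk crest in blue. For pdgfra, dlx2a and mafba all cardiac crest libraries lie above all trunk crest libraries, and for dct, gch2, hoxb9a and pax7b they lie below. The actc1b points, chosen after their values were seen, show cardiac crest replicate 3 among the trunk crest libraries.

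The core crest list did not move as a whole (median 0.26, camera adjusted p = 0.884), with 5 of 18 higher, 5 lower and 8 short of the test, and 7 higher and 6 lower when adjusted over the list alone. The paired-box genes pax7b (-3.65 ± 0.34) and pax7a (-3.70 ± 0.38) were lower, and the Myc family gene mych was higher (2.31 ± 0.39). Cardiac crest had 10038 ± 2549 scaled sox10 reads and trunk crest 25372 ± 336 (-1.37 ± 0.23, limma adjusted p = 0.00312). For ets1 (0.78 ± 0.33, limma adjusted p = 0.124) and tfap2a (-0.24 ± 0.18, limma adjusted p = 0.375) no difference was called. Among ectomesenchyme and arch genes 18 of 25 rose and 0 fell, 19 rose when adjusted over the list alone, and the median was 5.79 (camera adjusted p = 7.90e-10; adjusted p = 0.0463 with an estimated correlation). The endothelial and arch gene fli1a was 3.74 ± 0.32 higher on the log2 scale. All 24 pigment genes fell, on both adjustments, with a median of -4.95 (camera adjusted p = 3.71e-19; adjusted p = 0.0121 with an estimated correlation). The arch and pigment lists were the 2 of 24 that passed with an estimated correlation. In the list of cardiac crest candidates 9 of 15 rose and 0 fell, 9 rose and 2 fell when adjusted over the list alone, and the median was 2.60 (camera adjusted p = 0.00413; adjusted p = 0.171 with an estimated correlation). Its members egr1 (3.49 ± 0.40) and foxc1b (3.32 ± 0.47) were higher. Members that the authors marked were chosen on these samples, so the list is not independent evidence. The authors' deposited table gives log2 fold changes of 8.93 for mafba, 3.76 for fli1a, 3.32 for egr1 and 3.26 for foxc1b, and an adjusted p of 0.0859 for ets1.

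Posterior Hox genes were lower, 6 of 13 falling and 0 rising, and 8 falling when adjusted over the list alone (median -2.79, camera adjusted p = 0.000498; adjusted p = 0.360 with an estimated correlation). Besides hoxb9a these included hoxb7a (-2.79 ± 0.27) and hoxb10a (-5.37 ± 0.51). With 1 gene at 0 reads in a group held at its bound, the list median was -2.92. Anterior Hox genes went both ways, hoxb1b rising (1.58 ± 0.42) and 2 of 4 falling, hoxd3a among them (-1.24 ± 0.22, 25.1% overlapped), and 1 rose and 3 fell when adjusted over the list alone (median -1.56, camera adjusted p = 0.125). These are 13 of 36 posterior and 4 of 14 anterior Hox genes of the lists, the rest matching no gene name or lying wholly inside another gene. The hoxb1b call was lost without cardiac crest replicate 1 (0.0600) or any 1 of the trunk crest libraries (0.0510 to 0.0694).

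Cell cycle genes were higher, 15 of 31 rising and 0 falling, 17 rising when adjusted over the list alone, with a median of 0.90 (camera adjusted p = 2.91e-05; adjusted p = 0.271 with an estimated correlation). The proliferation marker mki67 was at 8891 ± 1184 and 2739 ± 249 (1.69 ± 0.20), the topoisomerase gene top2a rose by 1.88 ± 0.25 and the cyclin gene ccnd1 by 1.40 ± 0.20. In the migration and matrix list 19 of 40 rose and 4 fell, 20 and 4 when adjusted over the list alone, with a median of 1.69 (camera adjusted p = 7.22e-06; adjusted p = 0.0955 with an estimated correlation). The fibrillar collagen gene col5a1 rose by 3.49 ± 0.25, and the membrane metalloprotease gene mmp17b fell (-4.00 ± 0.33). Of 20 FGF genes 11 rose and 1 fell, 13 and 1 when adjusted over the list alone, with a median of 1.76, or 1.88 with 2 genes at their bound (camera adjusted p = 6.32e-05; adjusted p = 0.123 with an estimated correlation), the receptor gene fgfr2 rising by 4.19 ± 0.36. Of 17 Wnt targets 11 rose and 0 fell, 12 when adjusted over the list alone, with a median of 1.28 (camera adjusted p = 0.000168; adjusted p = 0.0761 with an estimated correlation), mycn among them (1.74 ± 0.20). Of 24 Notch genes 12 rose and 0 fell on both adjustments, with a median of 1.29 (camera adjusted p = 0.000586; adjusted p = 0.171 with an estimated correlation), notch2 (2.85 ± 0.40) and lfng (1.93 ± 0.28) among them.

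In the retinoic acid list 13 of 27 rose and 1 fell, 14 and 1 when adjusted over the list alone, with a median of 1.21 (camera adjusted p = 0.000713; adjusted p = 0.0753 with an estimated correlation). The gene that fell was crabp2b, a retinoic acid binding protein gene (-4.80 ± 0.24), while meis3, a homeobox cofactor gene, rose (2.22 ± 0.20). In the BMP and TGF-beta list 7 of 27 rose and 1 fell, 8 and 1 when adjusted over the list alone, bmp5 rising by 6.61 ± 0.72 (median 0.36, camera adjusted p = 0.0457; adjusted p = 0.360 with an estimated correlation). That call was lost without any 1 of the cardiac crest libraries (0.0523 to 0.0840) or without trunk crest replicate 2 (0.0736). Early-response and stress genes went both ways, 9 of 29 rising and 4 falling, 12 and 5 when adjusted over the list alone (median 0.68, camera adjusted p = 0.213, and 0.0430 without cardiac crest replicate 3). The heat shock gene hsp70l fell from 101077 ± 24843 scaled reads in trunk crest to 2911 ± 765 in cardiac crest (-5.12 ± 0.27), and ier2b, 16.83% overlapped, rose (3.25 ± 0.39).

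Lists of other tissues were mostly higher in cardiac crest at the preset correlation. They cover cells other than crest that the dissected tissue or the sort gate could hold. Which cells held these transcripts was not tested. In the neural tube list 13 of 23 rose and 0 fell, 18 when adjusted over the list alone, with a median of 4.66, or 4.78 with 5 genes at their bound (camera adjusted p = 1.35e-06; adjusted p = 0.0753 with an estimated correlation), zic1 rising by 4.66 ± 0.50. In the placode and ear list 9 of 16 rose and 1 fell, 12 and 1 when adjusted over the list alone, with a median of 5.10 (camera adjusted p = 4.06e-05; adjusted p = 0.0726 with an estimated correlation), oc90, an otolith matrix gene, rising by 3.33 ± 0.41. Of 19 cardiac mesoderm genes 4 rose and 1 fell on both adjustments (median 2.33, camera adjusted p = 0.0342; adjusted p = 0.359 with an estimated correlation; 0.1001 without trunk crest replicate 3). Of 10 endoderm genes 4 rose and 1 fell, 4 and 2 when adjusted over the list alone (median 2.203, camera adjusted p = 0.0355; adjusted p = 0.267 with an estimated correlation). That list was lost without cardiac crest replicate 3 (0.0525) or trunk crest replicate 2 (0.0592). Its member foxa2, with 0 reads in trunk crest, was at least 402-fold higher, and was also the 1 of 12 notochord and floor plate genes that rose, on both adjustments (median 1.62, camera adjusted p = 0.0434; adjusted p = 0.380 with an estimated correlation). The notochord list was lost without cardiac crest replicate 3 (0.114) or trunk crest replicate 2 (0.128) or 3 (0.0671). Of 20 endothelial and blood genes 3 rose, kdrl among them (3.76 ± 0.69), and 0 fell, on both adjustments (median 1.29, camera adjusted p = 0.0480; adjusted p = 0.331 with an estimated correlation). Leaving out cardiac crest replicate 1 (0.0863) or trunk crest replicate 2 (0.124) ended that call.

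Neural and glial derivative genes did not pass as a list, with 7 of 24 rising, the myelin gene plp1a (7.04 ± 1.24) among them, and 2 falling, 7 and 3 when adjusted over the list alone (median 0.63, camera adjusted p = 0.329). Nor did epidermis, with 3 of 13 rising and 1 falling on both adjustments (median 1.07, camera adjusted p = 0.0808, and 0.0252 without trunk crest replicate 3), the claudin gene cldni rising by 9.39 ± 0.62 and the cadherin gene cdh1 falling (-2.22 ± 0.29). Of 91 tested genes in the ribosomal protein list, S6 kinases included, 1 rose and 0 fell, 0 when adjusted over the list alone (median -0.08, camera adjusted p = 0.308, and 0.0159 without cardiac crest replicate 1 or 0.0352 without trunk crest replicate 1). In the somite and muscle list 2 of 23 rose and 2 fell on both adjustments, with a median of -3.48 (camera adjusted p = 0.0175; adjusted p = 0.380 with an estimated correlation). The somite genes tcf15 (2.74 ± 0.50) and meox1 (6.83 ± 1.32) rose, and the muscle parvalbumin gene pvalb1, 35.71% overlapped, fell (-8.43 ± 0.84). Muscle transcripts were in every trunk crest library and also in cardiac crest replicate 3: actc1b, chosen after its values were seen, was at 142, 361 and 231005 scaled reads in cardiac crest and at 550666, 155662 and 226034 in trunk crest. Not all followed in that replicate, since tnni2a.4 was at 2.8, 1.5 and 1.4 and pvalb1 at 0, 4.6 and 2.2 in cardiac crest. Whether crest cells or other cells in the trunk crest sorts held the muscle transcripts was not tested.

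Genes higher in cardiac crest than in both other groups numbered 12 among 19318 tested in both comparisons, where independent lists would share 6.54. They were gh1, the semaphorin receptor gene nrp2a (1.22 ± 0.25 against trunk crest), the retinoid receptor gene rxraa (3.05 ± 0.31), the cadherin gene cdh6 (2.76 ± 0.20), adgrg6, cetp, kctd15a, vps13d, ramp2, dlc1 and 2 genes with provisional names. For gh1 a transgene source of the reads stays open. The receptor gene adgrg6, 53.56% overlapped, stood at 3.04 ± 0.56 against non-crest and 5.07 ± 0.93 against trunk crest, and cetp at 2.88 ± 0.46 and 4.36 ± 0.51. Both comparisons use the same cardiac crest libraries, which the value for independent lists leaves out of account. Another 16 genes were higher than in non-crest but lower than in trunk crest, where independent lists would share 7.25. The excess over 6.54 is therefore not particular to genes higher in both. In 20 simulated sets of unchanged libraries the highest number higher in both was 0, but edgeR and limma called at most 1 gene higher in either comparison there, so that value is no measure for lists of this size. Fold changes of the 2 comparisons had a correlation across genes of 0.0377, where the simulated sets averaged 0.474, and a covariance of 0.0760, where the simulated covariance was 0.318 and observed minus simulated was -0.242. Genes are not independent replicates. With 3 cardiac crest libraries the shared group cannot be split, so part of the overlap may come from sharing them. Leaving out cardiac crest replicate 1 or 2 left 1 gene, leaving out non-crest replicate 1 or 2 gave 7 or 6, and leaving out non-crest replicate 3 gave 18. With the replicate number as a block fewer genes were higher in both, and only part of the 12 were among them, as given below.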

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

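Alternatives named here as added were chosen after seeing the data, and where a value moved the cause was not tested unless said. Against non-crest, a threshold of 0.01 left 97 genes (16 higher, 81 lower) of 294 (57, 237). DESeq2 called 1050 (297, 753), all 294 among them, and a test against a log2 fold change of 1 left 198 (30, 168). Leaving out each library in turn, with fewer samples, gave between 93 and 361 genes (14 to 74 higher, 78 to 308 lower), and leaving out replicate 3 of both groups, added, gave 752 (140, 612). RLE and upper-quartile scaling, limma-voom, other filters and leaving out genes that share bases with another (added) gave between 223 and 315. Against trunk crest, a threshold of 0.01 left 2266 genes (909, 1357) of 4829, and the test against a log2 fold change of 1 left 1364 (594, 770). Leave-one-out fits gave between 3205 and 4591 genes (1333 to 1869 higher, 1814 to 2722 lower). All other alternatives stayed within 1.5 times, from 3372 with limma without trend and robust prior (added) to 5954 with DESeq2, with 4546 by edgeR on the recovered reads (added). Upper-quartile factors (2669 higher, 2307 lower) moved the median over all genes from 0.14 to 0.26 on the log2 scale, a shift smaller than any called change the report names in that comparison (0.79 or more in size, dlc1), and 0 of the named genes changed direction in any setting. For this table a run without a low-value filter was not made, since the main test adds no filter to the listed genes. The 11106 genes that the deposited table omits could not be tested against trunk crest. With a replicate block, 284 genes (50, 234) differed from non-crest and 4273 (1978, 2295) from trunk crest. Among the 284 were 221 of the 294 main calls, 39 of the 57 higher and 182 of the 237 lower. With that block 12 and 16 lists passed, and 9 genes were higher in both, 5 of them among the 12. Same-numbered libraries deviated together with correlations of 0.0299, 0.0528 and 0.1596 against non-crest and 0.0091, 0.0274 and -0.0046 against trunk crest, so the numbers were not taken to pair libraries, although same-numbered cardiac crest and non-crest libraries come from the same tissue and have adjacent library numbers. Some genes given below, such as uts2d and hoxd10a, were high in both libraries of the same replicate number, so paired sorts are not excluded. The main test would leave such pairing out of account. The block ended the calls of the BMP (0.0528) and endothelial (0.0511) lists against trunk crest and brought the placode list past 0.05 against non-crest (0.0425). Upper-quartile factors (added for lists) ended the cardiac mesoderm (0.0518), endothelial (0.0626) and notochord (0.0617) calls against trunk crest, leaving 15 of 18. With an estimated correlation, camera called 0 of 24 lists against non-crest, where 5 had an unadjusted p below 0.05, and 2 against trunk crest. The number of lists called ranged from 8 to 14 of 24 against non-crest and from 14 to 19 against trunk crest as single libraries were left out. Genes higher in both comparisons numbered 1 at 0.01, 90 with DESeq2, 22 with limma-voom, 44 without replicate 3 of cardiac crest and non-crest (added), and from 1 to 18 in leave-one-out fits. Lists that changed direction had no call in the main test. Against non-crest, the ribosomal protein list pointed up without replicate 3 of both groups (adjusted p = 1.10e-06), without non-crest replicate 3 (0.0358) and without cardiac crest replicate 3 (0.0773), and down without cardiac crest replicate 1 (0.0402) or non-crest replicates 1 (0.4399) and 2 (0.0135). Cell cycle genes pointed down without cardiac crest replicates 1 (0.834) or 3 (0.709), non-crest replicates 1 (0.947) or 3 (0.819), or replicate 3 of both (0.449). Notochord genes pointed up without cardiac crest replicate 1 (0.834) or 2 (0.906) or non-crest replicate 1 (0.654). FGF targets pointed down without cardiac crest replicate 2 (0.930), neural and glial genes up without non-crest replicate 2 (0.877), migration genes down without it (0.968), and posterior Hox genes up without non-crest replicate 3 (0.966). Their lowest adjusted p over the fits with libraries left out, in the main direction, was 0.267 for notochord genes, 0.267 for FGF targets, 0.0269 for neural and glial genes, 0.156 for migration genes and 0.00954 for posterior Hox genes. Against trunk crest, core crest genes pointed down without cardiac crest replicate 1 (0.940) or 2 (0.876), with 0.604 as the lowest value, and the ribosomal protein list up without cardiac crest replicate 3 (0.172), in a range from 0.0159 to 0.685. Of the named genes that passed, 20 of 31 against non-crest and 4 of 61 against trunk crest lost their call in at least 1 leave-one-out fit. In libraries simulated at the observed depth and spread, 3 per group, 0% of the genes changed 2-fold were called in either comparison, and neither depth nor replicate number was varied. That simulation changed 200 genes by a known fold, where 4829 passed in the real trunk comparison. The adjusted threshold is less strict with so many, so the share does not describe the trunk comparison.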

Other observations

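Of the explanations tested here, the pituitary and silent-gene tests and the counts of other splits were fixed before the result was seen, and the tests of transgene reads, genomic expression, the 3 explanations of the muscle pattern and uncounted reads were chosen after it.

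Several genes stood between the other groups, higher in cardiac crest than in non-crest and lower than in trunk crest. They numbered 16, and 7 without cardiac crest replicate 1 or 2 and 9 without non-crest replicate 1, fits added after the count was seen. Among the 16 were sox10 and mocos, and pcbd1, qdpra and tspan36 were chosen after their values were seen. The pterin dehydratase gene pcbd1 was 2.05 ± 0.35 higher than in non-crest on the log2 scale and stood at -2.69 ± 0.28 against trunk crest. For the pterin reductase gene qdpra the values were 2.77 ± 0.34 and -2.55 ± 0.25, for mocos 6.68 ± 1.09 and -6.46 ± 0.28, and for the tetraspanin gene tspan36 2.40 ± 0.39 and -3.91 ± 0.30. Genes lower in both numbered 23, and 10, 8 and 82 without cardiac crest replicate 1, 2 or 3 and 12 without non-crest replicate 2. Genes lower than non-crest but higher than trunk crest numbered 18, and 3 and 1 without cardiac crest replicate 1 or 2 and 34 without non-crest replicate 3. Independent lists would share 7.25, 22.5 and 20.3 genes in these 3 directions, values that leave out of account the cardiac crest libraries both comparisons use.

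Single libraries, or those of 1 replicate number, stood out in the genes of this paragraph, chosen after their values were seen and not from a fixed list. In cardiac crest replicates 1, 2 and 3, s100t was at 112, 0.21 and 0 CPM and OTOF, a hair cell synapse gene, at 10.3, 0.62 and 0.40 CPM. The vesicular acetylcholine transporter gene slc18a3a was at 10.04 CPM in cardiac crest replicate 2 and 11.1 in non-crest replicate 2, with at most 1.14 in the other 4 libraries, and the urotensin gene uts2d at 16.7 and 14.3 CPM in those 2. The choline transporter gene slc5a7 was at 11.01 CPM in cardiac crest replicate 2 but 1.95 in non-crest replicate 2. In non-crest replicate 3 the apolipoprotein gene apoa2 was at 166 CPM, against 0.95 and 2.64 in the other non-crest libraries, and the mesoderm gene tbx6 at 25.1 CPM, against 0.22 and 1.18. Replicate 3 of both groups was high in hoxd10a (3.27 CPM in cardiac crest and 21.65 in non-crest, at most 0.06 in the other 4 libraries), hoxb10a (4.91 and 18.09, at most 1.61), myog (30.98 and 113.68, at most 8.77) and myod1 (55.94 and 129.3, at most 27.44). Genes over 8-fold above both other libraries of their group numbered 145 in cardiac crest replicate 3, 59 in non-crest replicate 2 and 49 in non-crest replicate 3, where 189 more were over 8-fold below.

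Growth hormone reads (gh1) reached 2519, 2736 and 968 CPM in the cardiac crest libraries. The other 8 measurable pituitary genes summed to at most 0.1305% of gh1 in any of them, which argues against pituitary cells in the sort, whose other hormones would come along. Only 2 gh1 reads lay in the 3 trunk crest libraries of the other fish line, and non-crest cells had 0.008545% of the cardiac crest level, where sox10 had 6.01%. Reads from a transgene carrying growth hormone sequence and expression from the genome in cardiac crest cells both allow these values. The test of genomic expression could fail only at a gh1 share above that of sox10, so the far lower share does not decide it. These explanations cannot be told apart, since line and crest level go together and the transgene sequence was not used here. Axial level and age stay open as untested explanations.

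Muscle transcripts filled cardiac crest replicate 3, where 11 of 12 contractile and creatine kinase genes, all 12 at 10 CPM or more in non-crest, were over 4-fold above both other cardiac crest libraries, by a median of 57.7% of their non-crest level. Epidermal genes exceeded the other libraries by a median of 0.5144% of theirs, which argues against unsorted tissue. A swap with non-crest replicate 3 is argued against by sox10, 8.87 times the highest non-crest library. Differentiated muscle cells among the sorted cells may account for the pattern, as a hypothesis, which the mCherry gate would have removed unless such cells carried the signal. Outside the 12, the muscle genes tnni2a.4 and pvalb1 were not raised in cardiac crest replicate 3, at 1.4 and 2.2 scaled reads. In the count table pvalb1 stayed below 10 CPM in every library, non-crest included, and the non-crest level of tnni2a.4 is not given here. These genes therefore cannot decide for or against that hypothesis. Replicate 3 of both groups has library numbers apart from the others (22028 and 22029, against 21309 to 21339) and shares the posterior Hox and myogenic transcripts given above, so a difference in the tissue taken stays open, untested, as does any biological explanation beyond cells in the sort.

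All 4819 genes wholly inside another gene had 0 reads in the 6 libraries of the count table. Silence of these genes is argued against by ribosomal protein genes, which every cell uses: 6 of 6 that lie inside another gene had 0 reads, while the others had a median of 476 CPM. Reads in overlapping genes left uncounted may account for this, and SOX2 and SOX3, wholly inside other genes, and foxd3, 98% inside, could not be measured. Beyond silence of the genes no biological explanation was tested.

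With 3 libraries against 3 there are 10 splits, the real one included, so a share under 0.1 cannot arise. Against non-crest the real split gave 294 genes, 57 higher and 237 lower, and the highest of the others 0, with 1 split of 10 as large in each case. For lists the real split gave 11 and the highest other 11, so 2 of 10 were as large. Against trunk crest the real values were 4829, 2233 and 2596 genes and 18 lists, and the highest others 0, 0 and 0 genes and 12 lists, with 1 of 10 as large in each case.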
